A study of Caenorhabditis elegans with 6 samples.

How the data were processed

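The 6 samples were Affymetrix C. elegans arrays hybridised with biotin-labelled cRNA, which per the labels' protocols was made from 10 to 100 ng of total RNA extracted with Trizol. Groups and replicate numbers were taken from the sample titles: 3 technical replicates of the space condition and 3 of the ground control. The deposited values are linear intensities, 1 per probe set and array. The tool by which the authors summarised probes, subtracted background and scaled the arrays is not given in the sources used here. The values themselves show a scaling, since the mean after trimming 2% at each end was 500.1 to 500.2 on each array. No raw scanner files were used here. Of 22625 probe sets, 77 array controls were left out of the tests and 22548 were tested. No filter on dim probe sets was applied in the main results, and 13.4% to 17.1% of the tested values on an array lay below 16. As a measure of background, 8 control probe sets for sequences that a worm sample should not hold had intensities of 0.562 to 86.7, with a median of 6.48. Levels in that range are close to background, and fold changes there are understated.

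Intensities were used as deposited on the scale log2(intensity + 16), because the array medians differed by less than 0.5 log2 units. Fold changes are on that scale, as space condition minus ground control, and the pseudocount lowers the change of dim genes. Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the sole factor and Benjamini-Hochberg adjustment over all 22548 probe sets, or over genes for tests by gene list alone. A probe set rose or fell if its adjusted p was under 0.05 and it differed at least 2-fold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The groups, the tests, the gene lists, the naming rule and most of the other settings were fixed before the data were examined.

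Gene symbols came from the platform annotation and were updated through gene identifiers to a RefSeq table of assembly WBcel235, which was used for names alone. Of the tested probe sets, 20766 had 1 symbol, 887 had several and 895 had none, and 20701 of those with 1 symbol were found in the RefSeq table. Probe sets with several symbols or none were tested and left unnamed. For each of 17118 genes, the probe set with the highest mean over the 6 arrays stood for the gene. Of 2981 genes with several probe sets, 366 had a call on at least 1, 67 had calls on all, and 0 had calls in opposite directions at that limma threshold. A mark for probes shared with other sequences was carried by 6711 probe sets. No genome was used here and no positions are given.

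The genes named were those picked by a rule. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean exceeded the median of all probe sets. From each list it took up to 4 members past the same threshold with the largest changes and the member with the highest level. It also took daf-16, daf-2, sod-3, unc-54, myo-3, hlh-1, vit-2, hsp-16.2, hsp-4, cep-1, egl-1 and col-19, whatever their values. Other genes are named as chosen after their values were seen.

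In all, 48 gene lists were tested. They covered collagens, moulting, hypodermis, body-wall muscle, pharynx, neurons, neuropeptides, chemoreceptors, intestine, gut proteases and lipases, vitellogenins, major sperm proteins, sperm, oocyte and eggshell, germline and meiosis, embryo, male and dauer genes. They also covered the cell cycle, histones, DNA repair, DNA damage response, apoptosis, insulin-like peptides, insulin signalling, DAF-16 targets and TGF-beta signalling. Stress and defence lists were small heat-shock and inducible Hsp70, ER stress, mitochondrial stress, oxidative stress, hypoxia, osmotic response, metal and haem, antimicrobial effectors, C-type lectins, cytochrome P450, glutathione S-transferases, UDP-glucuronosyltransferases and ABC transporters. The remaining lists were fat metabolism, carbohydrate metabolism, TCA cycle and respiratory chain, ribosome, proteasome, transthyretin-like proteins, nuclear hormone receptors and F-box proteins. Each was tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 48 lists, and again with an estimated correlation. The latter form takes p from the few residual degrees of freedom of the arrays, so it is stricter at equal correlation. A further comparison set each list's median against 10000 random lists of the same size matched on mean level.

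Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, filters on dim probe sets, an intensity trend in the variance, the replicate number as a block, leaving out probe sets with marks of shared probes, a 1.5-fold minimum inside the test and leaving out each array. A covariate made of the mean log2 5'/3' ratio of the actin and Gapdh controls, and the removal of space condition 1 and ground control 3 together, were added after seeing the data. The test was also tested on simulated data for the same comparison with 200 of 22548 probe sets changed. It recovered 8% of changes of 1 log2 unit and 93% of changes of 2 log2 units with 3 false calls. Far more probe sets passed in the data (2042), where the same adjustment admits larger p-values. These percentages therefore do not give the recovery in the data. In that simulation 0 lists without a shift passed camera, and a list shifted by 0.5 log2 units had an adjusted p of 1.13e-16. Each probe set was drawn independently there, whereas the estimated correlation in the data reached 0.84 for the ribosome list. The simulation therefore cannot show how often camera calls lists of correlated genes without a shift.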

Results

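Transcript levels were measured in Caenorhabditis elegans of the laboratory strain CC1, grown in CeMM, a bacteria-free liquid medium. Worms lived on the International Space Station, passed by an automatic device from chamber to chamber at intervals of about 1 month for up to 10 generations. Ground worms were passaged on the same schedule. The flown worms were of mixed ages. Total RNA was measured on 6 Affymetrix arrays, 3 labelled as technical replicates of the space condition and 3 of the ground control. The sources do not say whether arrays of a group shared an RNA extract or differed in extraction, labelling or hybridisation alone, nor how many cultures each group came from. The p-values therefore measure only the spread between these arrays, which may be technical, and they compare these arrays' RNA rather than spaceflight with ground conditions in general. The number of arrays limits the precision. Deposited intensities had array medians of 111.9 to 119.3 on the space arrays and 102.5 to 128.1 on the ground arrays, with a 2%-trimmed mean of about 500 on each array.

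Arrays of the same group correlated at 0.960 to 0.976 over probe sets on the log2 scale, and arrays of different groups at 0.926 to 0.952. The first principal component held 45.1% of the variance and placed the 3 space arrays apart from the 3 ground arrays. The second, with 20.9%, placed replicate 1 of both groups apart from the other arrays. The array's own actin controls also differed between the groups. The log2 ratio of the 5' over the 3' actin probe set was -3.12 ± 0.164 on the space arrays and -3.97 ± 0.358 on the ground arrays (SD, n = 3 each), without overlap. The same ratio for Gapdh overlapped between the groups and was lowest on ground control 3, at -3.65.

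**Figure D1:**
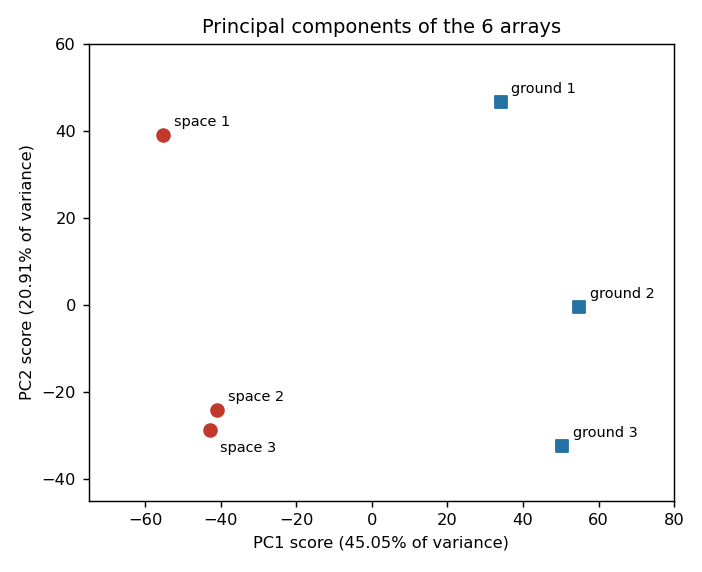
Scores of the 6 arrays on the first (x axis) and second (y axis) principal components of the log2 values of 22548 probe sets, in score units, with space condition arrays as circles and ground control arrays as squares. The first component (45.05% of variance) separates the groups, and the second (20.91%) places replicate 1 of each group highest.

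The comparison asked which transcripts differed between the flown worms and those kept on the ground. The largest rise among the genes chosen by rule was that of nspe-7, a member of a nematode-specific peptide family, from 570 ± 47.6 on the ground arrays to 14348 ± 2280 on the space arrays (mean ± SD, n = 3 each). Its log2 fold change was 4.61 ± 0.21 (SE, adjusted p = 0.000613, limma). Its relative nspe-5 rose by 3.10 ± 0.20. The C-type lectin gene clec-76 rose by 3.69 ± 0.24, the alcohol dehydrogenase gene adh-1 by 3.36 ± 0.27 and the ammonium transporter gene amt-4 by 3.28 ± 0.23. The cathepsin B-like protease gene cpr-2 rose by 3.10 ± 0.27, from an intensity of 1502 to 12684. Others among the 12 largest rises were the infection response gene irg-5 (3.23 ± 0.22), the glutathione S-transferase gene gst-26 (2.93 ± 0.24), ZK1320.2, F42A10.6, Y26D4A.21 and Y47H9C.1.

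The largest fall among the genes chosen by rule was that of cnc-3, which encodes a caenacin, an antimicrobial peptide of the epidermis, from 1280 ± 355 on the ground arrays to 49.9 ± 12.7 on the space arrays. Its log2 fold change was -4.28 ± 0.27 (adjusted p = 0.000886). A second caenacin gene, cnc-4, fell from 5185 to 587 (log2 fold change -3.11 ± 0.20), and nlp-25, a related peptide gene, changed by -3.16 ± 0.26. The chemoreceptor-family gene str-112 changed by -3.59 ± 0.26, the lipase-related gene lips-10 by -2.90 ± 0.21 and spi-2, named for serine protease inhibitors, by -2.86 ± 0.19. The 12 largest falls also held F23F12.12 (-3.64 ± 0.23), C15A11.7, ifas-1, B0478.3, bus-17 and F26A1.3. Of 148 named genes with a call, 49 had 1 group mean no higher than the brightest control for absent sequences (86.7), and the size of such changes depends on the pseudocount. The probe sets of nspe-7, nspe-5, ZK1320.2, amt-4, cnc-3, F23F12.12 and lips-10 carry a mark of probes shared with other sequences.

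Across the array, 2042 of 22548 probe sets differed at an adjusted p under 0.05, 1416 higher and 626 lower on the space arrays. Of these, 1648 also differed at least 2-fold, of which 1162 rose and 486 fell. With 1 probe set per gene, 913 of 17118 genes rose and 414 fell. Rises made up 70.5% of the 2-fold differences on the deposited scaling and 58.9% after quantile normalization. All 3 arrays of one group lay above all 3 of the other in 30.2% of probe sets, against 10% by chance. Leaving out 1 array lowered the 1648 probe sets to 588 without space condition 3, 604 without space condition 2 and 879 without space condition 1. It gave 928 without ground control 2, 1132 without ground control 3 and 1201 without ground control 1. Without both space condition 1 and ground control 3, limma called 0 probe sets, with 5176 at an unadjusted p under 0.05. Of 48 gene lists, 18 passed the set test camera, 9 upward and 9 downward, and 1 did so with an estimated correlation. The other 9 splits of the 6 arrays into 3 and 3, which keep part of the group difference, passed 4 to 13 lists.

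**Figure D2:**
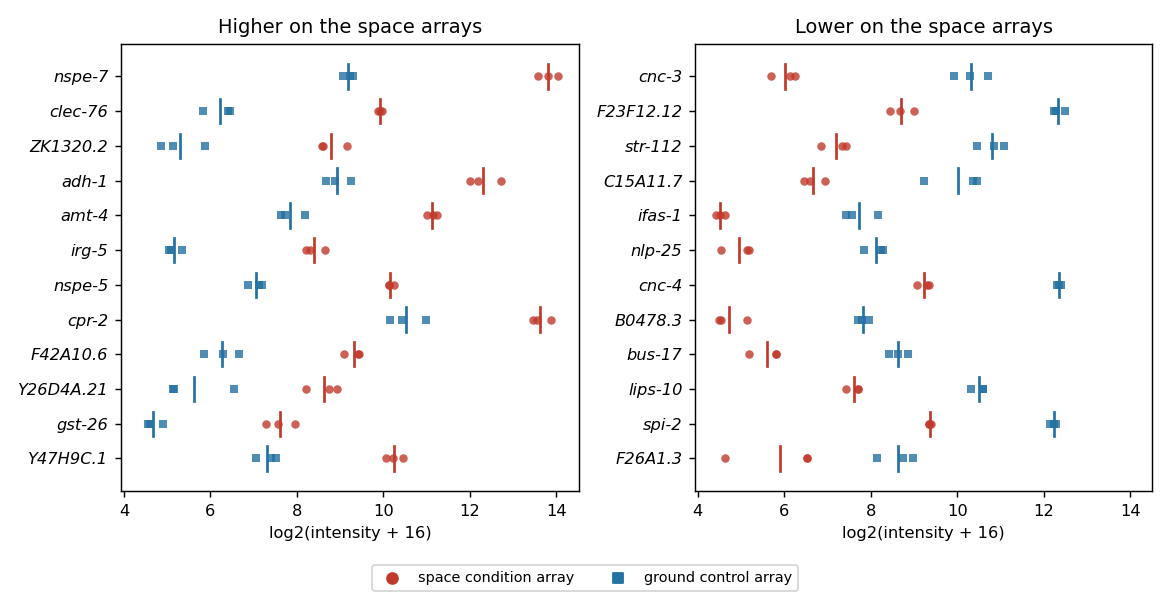
Values of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) on each array, as log2 of the deposited intensity plus 16 (x axis), with circles for the 3 space condition arrays, squares for the 3 ground control arrays and vertical bars for group means. The space arrays lie above the ground arrays for each gene at left and below them for each gene at right, with nspe-7 4.61 log2 units higher and cnc-3 at -4.28.

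Lists of germline genes had higher medians on the space arrays. Of 43 measured genes of the germline and meiosis list, 24 rose and 0 fell, with 28 and 0 adjusted over the list alone and a median log2 fold change of 1.17. The crossover gene cosa-1 rose by 2.07 ± 0.30, him-14, which encodes a MutS homologue of meiosis, by 1.87 ± 0.28, the Piwi gene prg-1 by 1.81 ± 0.23 and the meiotic checkpoint gene pch-2 by 1.81 ± 0.24. The brightest member, the poly(A) polymerase gene gld-2, did not pass, at -0.84 ± 0.27 (adjusted p = 0.0972). Of 23 major sperm protein genes, which encode the motility protein of nematode sperm, 14 rose and 0 fell (15 and 0 adjusted over the list alone; median 1.27). Examples were msp-55 (2.15 ± 0.53), which after quantile normalization stood at 2.055 with an adjusted p of 0.0812, msp-77 (1.70 ± 0.23) and msp-65, the brightest, at 1.31 ± 0.27. Each of these genes was read by probe sets marked as shared, so single members cannot be told from their relatives. In the oocyte and eggshell list, 10 of 32 genes rose and 0 fell (12 and 0 adjusted over the list alone; median 0.84). These included the eggshell genes cbd-1 (2.29 ± 0.36) and cpg-2 (1.38 ± 0.20) and the RNA-binding protein genes puf-11 (1.94 ± 0.33) and cey-3 (1.80 ± 0.25). The brightest, the kinase gene mbk-2, stood at -0.48 ± 0.23 (adjusted p = 0.239). Of 28 other sperm genes 2 rose and 0 fell, also when adjusted over the list alone, namely spe-11 (1.84 ± 0.26) and ssp-16 (1.51 ± 0.28). The ground mean of spe-11 (4.23) lay below the median of absent control sequences (6.48), and its change came to 3.55 with a pseudocount of 1 and to 0.82, short of 2-fold, with a pseudocount of 64. The adjusted p of limma's camera was 5.8e-15 for germline and meiosis, 3.83e-12 for major sperm proteins, 2.83e-09 for oocyte and eggshell and 0.0347 for sperm. The first 3 lists had an adjusted p = 0.109 with an estimated correlation and sperm an adjusted p = 0.543 with an estimated correlation, so none of the 4 calls held in that form. Before adjustment, limma found 1 lower gene at p under 0.05 in the germline and meiosis list, 1 in the sperm list and 0 in the other pair. The sperm list did not pass camera without ground control 1 (median 0.21), without probe sets marked as shared (0.26) or without both space condition 1 and ground control 3 (0.44). The germline lists, and the cuticle lists in the opposite direction, differed along with the actin 5'/3' ratio, which was 0.85 log2 units higher on the space arrays.

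Cell division lists had higher medians too. In the cell cycle list, 19 of 58 genes rose and 2 fell (24 and 2 adjusted over the list alone), with a median of 0.83. The mitotic kinase genes air-1 (1.80 ± 0.21) and cdk-1 (1.69 ± 0.28) and the ribonucleotide reductase gene rnr-1 (1.69 ± 0.28) were among the 4 largest changes. The centrosome gene spd-5 rose by 1.69 ± 0.35 on its brighter probe set and stood at -0.34 on a dimmer one. This was the single list past the test both with the preset correlation (camera adjusted p = 3.83e-12) and with an estimated correlation (adjusted p = 0.0441). In the DNA repair list 12 of 43 genes rose and 1 fell (13 and 1 adjusted over the list alone; median 0.60; camera adjusted p = 4.16e-07, and adjusted p = 0.118 with an estimated correlation). The translesion polymerase gene polh-1 rose by 2.89 ± 0.31, the uracil-DNA glycosylase gene ung-1 by 2.38 ± 0.21, the recombinase gene rad-51 by 1.51 ± 0.21 and the excision repair nuclease gene xpf-1 by 1.33 ± 0.22. The ground means of polh-1 (10.4) and ung-1 (13.8) lay among those of absent control sequences, and with pseudocounts of 64 and 1 their changes came to 1.72 and 4.02 for polh-1 and 1.38 and 3.26 for ung-1. Of 19 genes of the DNA damage response list 3 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.70; camera adjusted p = 0.0183, and adjusted p = 0.21 with an estimated correlation). They were the checkpoint genes hpr-9 (1.48 ± 0.37) and hpr-17 (1.12 ± 0.27) and cep-1, the worm homologue of p53, at 1.38 ± 0.28. None of these 3 calls held after quantile normalization (hpr-9 at 1.38, hpr-17 at 1.06 and cep-1 at 1.21), with adjusted p = 0.084, 0.0655 and 0.0537. Without marked probe sets hpr-9, read by the same probe set, kept its value of 1.48 with an adjusted p of 0.059 over the fewer probe sets tested. A dimmer probe set of cep-1 stood at -0.02. The apoptosis activator gene egl-1 did not pass, at -0.49 ± 0.20 (adjusted p = 0.174). Of 36 histone and linker histone genes 6 rose and 0 fell, also over the list alone (median 0.39; camera adjusted p = 0.000311, and adjusted p = 0.543 with an estimated correlation). The linker histone genes hil-4 (2.68 ± 0.44), hil-2 (2.17 ± 0.31) and hil-5 (1.60 ± 0.23) were 3 of these. Lower genes at an unadjusted p under 0.05 in limma numbered 2 in the damage list and 1 in the histone list. The damage list did not pass camera without ground control 2 (median 0.51) or without marked probe sets (0.71), and the histone list not without marked probe sets (0.21).

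Lists of genes of the cuticle and the epidermis beneath it had lower medians on the space arrays. Of 148 genes of the collagen list 15 fell and 0 rose, also over the list alone, with a median of -0.28. One of the 15, dpy-18, encodes a collagen-modifying enzyme and no collagen; without it 14 of 147 genes fell, 34 were higher and the median was -0.27. On the brightest probe set of each gene, the collagen genes col-113 (-2.69 ± 0.31), col-97 (-2.09 ± 0.27), sqt-2 (-2.02 ± 0.24) and rol-6 (-1.87 ± 0.42) had the largest falls, while the brightest, col-106, stood at -0.37 ± 0.21 (adjusted p = 0.338) and the adult collagen gene col-19 at -0.08 ± 0.27 (adjusted p = 0.897). Of 35 moulting genes 6 fell and 0 rose, also over the list alone, with a median of -0.52. They included the cuticulin gene cut-3 (-1.74 ± 0.26), the fibrillin-related gene fbn-1 (-1.59 ± 0.23) and mlt-8 (-1.52 ± 0.27). With a space mean of 12.4, in the range of absent controls, mlt-8 stood at -2.33 with a pseudocount of 1 and -0.77, short of 2-fold, with a pseudocount of 64, and it lost its call in 8 of 16 alternatives, among them leaving out space condition 1, 2 or 3 or ground control 2. The endocytic receptor gene lrp-1 was lower at -0.94 ± 0.19 (adjusted p = 0.0264), short of 2-fold. In the hypodermis list, 2 of whose 26 genes (the collagen gene dpy-7 and dpy-18) were also in the collagen list, 2 fell and 0 rose, also over the list alone (median -0.32). Both, dpy-18 (-1.2 ± 0.22) and pdi-2 (-1.2 ± 0.29), encode parts of the enzyme that hydroxylates collagen. Without marked probe sets pdi-2 stood at -0.99 (adjusted p = 0.0856). Of 19 genes of the TGF-beta signalling list 3 fell and 0 rose, also over the list alone (median -0.42), with the body length gene lon-1 at -2.29 ± 0.28, daf-5 at -1.11 ± 0.21 and kin-29 at -1.05 ± 0.20. On a probe set without the mark of shared probes daf-5 stood at -0.37 (adjusted p = 0.74). The TGF-beta list did not pass camera without both space condition 1 and ground control 3 (median -0.27). In the osmotic response list 5 of 16 genes fell and 0 rose, also over the list alone (median -0.55). These included the inositol transporter gene hmit-1.1 (-2.35 ± 0.27) and 2 epidermal peptide genes, nlp-29 (-2.01 ± 0.20) and nlp-27 (-1.78 ± 0.25). The camera adjusted p was 2.12e-06 for collagens, 6.63e-05 for moulting, 0.00222 for hypodermis, 0.00189 for TGF-beta signalling and 0.00189 for the osmotic response. None of the 5 calls held with an estimated correlation, with adjusted p = 0.109 for collagens, 0.127 for moulting, 0.127 for hypodermis, 0.365 for TGF-beta signalling and 0.118 for the osmotic response. Without adjustment, limma found 2 higher genes of the collagen list at p under 0.05, 1 higher gene in the osmotic list and 0 in the other 3 lists.

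**Figure D3:**
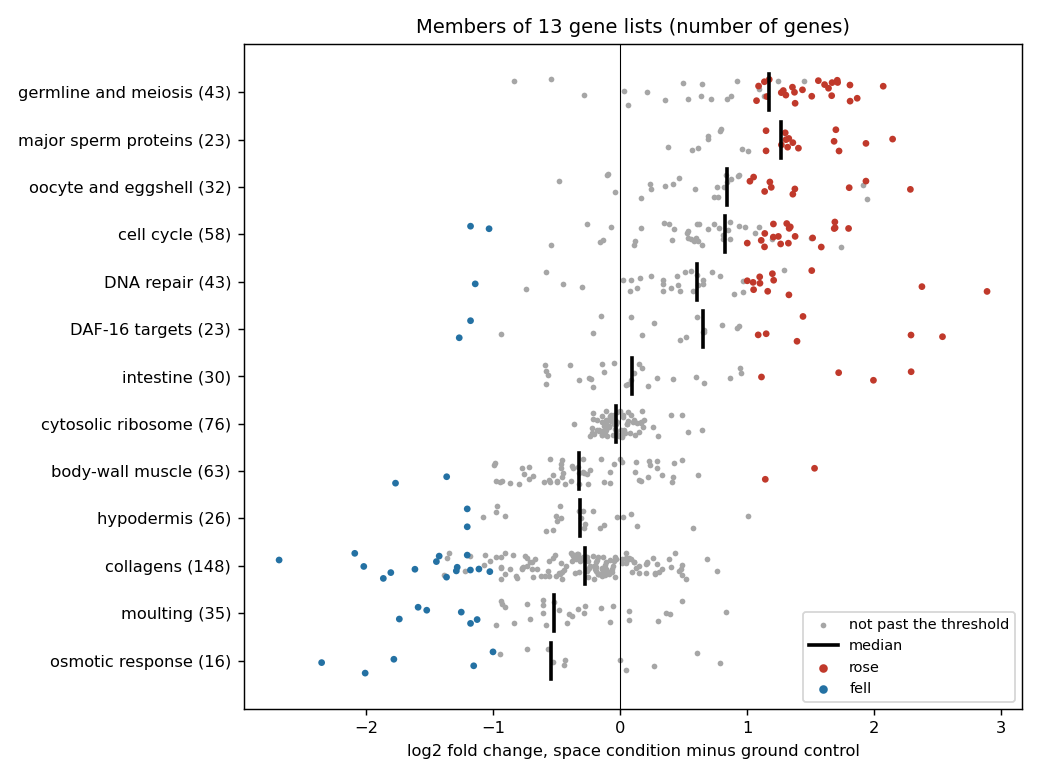
Log2 fold changes, space condition minus ground control (x axis), of the members of 13 gene lists (rows, with the number of measured genes), where each point is 1 gene, coloured red if it rose, blue if it fell and grey otherwise, and black bars mark medians. Medians run from 1.27 for major sperm proteins and 1.17 for germline and meiosis to -0.55 for the osmotic response, and the ribosome list, at -0.04, turns to 0.10 after quantile normalization.

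Few muscle and nerve genes passed singly. Of 63 genes of the body-wall muscle list 2 rose and 2 fell, also over the list alone, with a median of -0.32 (camera adjusted p = 0.00185, and adjusted p = 0.109 with an estimated correlation). This list also holds pharyngeal muscle genes that are in the pharynx list too. The alpha-actinin gene atn-1 fell, at -1.77 ± 0.19, from 4952 to 1443. The gene mua-3, which anchors muscle attachments in the epidermis, fell at -1.37 ± 0.20 on a probe set marked as shared and stood at 0.03 on another. The myosin heavy chain gene myo-3 rose by 1.53 ± 0.27 and the calponin-related gene cpn-3 by 1.14 ± 0.25. The main body-wall myosin gene unc-54 stood at -0.46 ± 0.31 (adjusted p = 0.428) and the muscle transcription factor gene hlh-1 at -0.34 ± 0.43 (adjusted p = 0.699). Of 88 neuron genes 1 fell, the synaptic vesicle GTPase gene rab-3 (-1.07 ± 0.21), and 0 fell adjusted over the list alone (median -0.13; camera adjusted p = 0.0106, and adjusted p = 0.543 with an estimated correlation). Another rab-3 probe set had the opposite sign. Of 1228 chemoreceptor genes 3 rose and 22 fell (1 and 4 adjusted over the list alone; median -0.17; camera adjusted p = 0.00222, and adjusted p = 0.741 with an estimated correlation). The chemoreceptor list did not pass camera without space condition 1 (median -0.07), without ground control 2 (-0.02), without space condition 1 and ground control 3 together (-0.08) or with the 5'/3' ratio as a covariate (-0.06), and the neuron list not without marked probe sets (-0.11). The ER stress list had a median of -0.34 (camera adjusted p = 0.0102, and adjusted p = 0.127 with an estimated correlation). In it 1 of 23 genes fell, pdi-2, and 0 fell adjusted over the list alone. Against random lists matched on level, neither the neuron list (adjusted p = 0.0964) nor the ER stress list (adjusted p = 0.0606) passed. At an unadjusted p under 0.05, limma found 11 lower neuron genes and 8 lower ER stress genes.

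Among genes tied to insulin signalling, targets of the transcription factor DAF-16 had a higher median. Of 23 such targets 6 rose and 2 fell, also over the list alone (median 0.65; camera adjusted p = 0.0015, and adjusted p = 0.109 with an estimated correlation). The saposin-like gene spp-1 rose by 2.54 ± 0.25 on a probe set marked as shared and stood at 0.75 (adjusted p = 0.294) on its other one. Other rises were those of dod-3 (2.29 ± 0.28), the transhydrogenase gene nnt-1 (1.44 ± 0.22) and the small heat-shock protein gene sip-1 (1.39 ± 0.26). The brightest target, the metallothionein gene mtl-1, stood at 0.66 ± 0.23 (adjusted p = 0.129) and the superoxide dismutase gene sod-3 at 0.47 ± 0.20 (adjusted p = 0.192). The regulators daf-16 (-0.02 ± 0.24, adjusted p = 0.978) and daf-2 (-0.45 ± 0.35, adjusted p = 0.493) did not pass. In the insulin signalling list 1 of 22 genes fell and 0 rose, also over the list alone: skn-1, a regulator of detoxification genes, at -1.14 ± 0.23 (camera adjusted p = 0.645). Among 24 insulin-like peptide genes 1 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.829), with ins-35 at 1.95 ± 0.34, ins-4 at -1.50 ± 0.20 and ins-6 at -1.27 ± 0.22. Of 15 small heat-shock and inducible Hsp70 genes 3 rose and 0 fell, also over the list alone (camera adjusted p = 0.168). One of them, hsp-16.2, rose by 1.09 ± 0.22, from 5575 to 11841. At an unadjusted p under 0.05, limma found 2 higher insulin signalling genes and 1 lower heat-shock gene. The ER chaperone gene hsp-4 stood at 0.31 ± 0.39 (adjusted p = 0.695).

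Defence genes moved in both directions. Of 93 antimicrobial effector genes 13 rose and 11 fell (13 and 13 adjusted over the list alone), and the list as a whole did not pass (median -0.06, camera adjusted p = 0.668). Its largest changes were those of irg-5, upward, and of cnc-3, nlp-25 and cnc-4, downward, with the values given for the largest changes of all genes. Among 220 C-type lectin genes 18 rose and 4 fell (20 and 4 adjusted over the list alone; camera adjusted p = 0.71). Besides clec-76, the largest rises were those of clec-52 (2.65 ± 0.31), clec-7 (2.24 ± 0.25) and clec-265 (2.22 ± 0.19). The brightest members of these lists, asp-1 (-0.13 ± 0.23, adjusted p = 0.798) and clec-63 (-0.20 ± 0.27, adjusted p = 0.717), did not pass.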

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

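The actin control probe sets, which lie outside the comparison of worm genes, differed between the groups. The log2 ratio of the 5' over the 3' actin probe set was higher by 0.85 on the space arrays (-3.12 ± 0.164 against -3.97 ± 0.358, SD, n = 3 each), with each space array above each ground array. Corresponding differences were 0.63 for Gapdh, 0.12 for catalase and 0.05 for ubiquitin, with overlapping arrays in each case.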

How the results depend on the processing

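The setting with the 5'/3' covariate and the one without space condition 1 and ground control 3 were chosen after seeing the data. The 2042 probe sets past the adjusted p became 1033 with a pseudocount of 1, 1005 without marked shared probes, 205 with a 1.5-fold minimum in the test, 1097 with the 5'/3' covariate and 0 without the 2 arrays. For the 1648 that also differed 2-fold the counts were 1027, 905, 205, 1097 and 0, and 952 in the upper 1/3 of mean level, where fewer probe sets were tested. At an unadjusted p under 0.05 limma gave 5176 probe sets without the 2 arrays, against 5553 with all 6. Leaving out 1 array gave 588 (without space condition 3) to 1201 (without ground control 1) for both counts, with fewer arrays to estimate the spread. Apart from the smaller sets and fewer arrays, the cause was not tested. All 1648 kept their sign in each setting that tested them all. They were chosen for large differences on these same arrays, so this says little on stability. Quantile normalization called 1319 of the 1648 among its 1501.

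Of 48 lists, 18 passed camera, 1 with an estimated correlation and 20 against random lists, 16 of them shared. Body-wall muscle (0.003), DAF-16 targets (-0.017) and osmotic response (-0.0592) lost their calls although their estimated correlations lay below the preset 0.01. The cell cycle list (0.00176) kept its call. A higher correlation between genes therefore does not account for the loss in those lists. With an estimated correlation, camera takes p from the few residual degrees of freedom of the arrays. With the preset one it takes p from the number of genes. The estimated form is thus stricter at equal correlation, and calls lost in it need not reflect the genes. How much of the loss this gives was not tested. Other settings gave 13 to 21. The ribosome list, at -0.04, turned to 0.10 after quantile normalization, 0.27 with the covariate and 0.29 without the 2 arrays, where it passed camera upward (adjusted p = 0.0425, 0.00108 and 2.05e-05). With 1 array left out it ranged from -0.17 to 0.21, the latter without ground control 3 (adjusted p = 0.00421). The cause was not tested. Without marked probe sets, spd-5 turned to -0.34 and mua-3 to 0.027, read by other probe sets. Of 148 named genes with a call, 139 kept it after quantile normalization, 110 with the covariate, 59 with the 1.5-fold minimum and 0 without the 2 arrays.

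The replicate number as a block gave 2226 and 1741 probe sets and 18 lists. Arrays with the same number deviated from their group means with correlations of 0.39, 0.06 and 0.17. Not every array correlated best with its own number: space condition 2 did so with ground control 3 (0.16). Signal near the background of absent sequences (median 6.48) limits what dim genes can show.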

Other observations

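Detoxification genes moved in both directions. Of 74 cytochrome P450 genes 9 rose and 1 fell (9 and 3 adjusted over the list alone), among them cyp-35B1 (1.96 ± 0.23), cyp-35B2 (1.92 ± 0.20) and cyp-37B1 (1.90 ± 0.24, SE). Of 45 glutathione S-transferase genes 6 rose and 4 fell (6 and 5 adjusted over the list alone), with gst-27 at 2.74 ± 0.29 and gst-29 at -1.78 ± 0.23. Of 64 UDP-glucuronosyltransferase genes 6 rose and 5 fell, with ugt-45 at -2.27 ± 0.25 and ugt-44 at 1.97 ± 0.37, and of 38 ABC transporter genes 1 rose and 4 fell. In the oxidative stress list 2 of 33 genes rose and 1 fell, with the nitrilase gene nit-1 at 1.41 ± 0.21 and the superoxide dismutase gene sod-1 at 1.2 ± 0.23. Of 24 metal and haem genes 3 rose and 1 fell, with the globin gene glb-1 at 2.16 ± 0.26 and the metal transporter gene smf-1 at -1.3 ± 0.20. Of 14 mitochondrial stress genes 1 rose and 1 fell, and of 17 hypoxia genes 0 passed limma, against 3 at an unadjusted p under 0.05.

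In metabolism, 3 of 57 fat genes rose and 3 fell, with the lysosomal lipase gene lipl-1 at 2.77 ± 0.22 and the fatty acid synthase gene fasn-1 at -1.2 ± 0.29. Among probe sets without marks of shared probes fasn-1 kept this value with an adjusted p of 0.0542. Of 31 carbohydrate genes 1 rose and 1 fell, the trehalase gene tre-5 (1.29 ± 0.20) and the gluconeogenesis gene pck-2 (-1.27 ± 0.23). Of 68 TCA cycle and respiratory chain genes 3 rose and 0 fell. Intestinal genes included 4 rises and 0 falls among 30, with the protease genes cpr-1 (2.29 ± 0.31) and cpr-4 (1.99 ± 0.26) and the peptide transporter gene pept-1 (1.72 ± 0.34). In the list of gut proteases and lipases 8 of 76 rose and 1 fell. Of 5 vitellogenin genes, which encode yolk, 1 fell and 0 rose, vit-5 at -2.08 ± 0.25, with a mean on the space arrays inside the range of absent control sequences (0.562 to 86.7), while vit-2 stood at 0.50 ± 0.23 (adjusted p = 0.237) with intensities of 135 and 91.6. Dauer genes had 3 rises and 2 falls among 26, male genes 2 and 1 among 23, embryo genes 1 and 1 among 32 and apoptosis genes 2 and 0 among 30. Transthyretin-like genes had 2 rises and 0 falls among 40, nuclear hormone receptors 4 and 7 among 259 (3 and 7 adjusted over the list alone) and F-box genes 21 and 4 among 311 (21 and 6).

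Housekeeping and signal peptide lists held few calls. Limma called 0 of 76 ribosome genes, 0 of 33 proteasome genes, 0 of 56 neuropeptide genes and 0 of 20 pharynx genes; the counts were 1, 6, 5 and 6 at an unadjusted p under 0.05. Their medians were -0.04, 0.22, -0.06 and -0.34. The proteasome, pharynx, ribosome and nuclear hormone receptor lists stood apart from random lists matched on level (adjusted p = 0.0277, 0.049, 0.00517 and 0.0298) although camera did not call them on the deposited scaling with all 6 arrays and no covariate, and the neuron and ER stress lists, which camera called, did not (adjusted p = 0.0964 and 0.0606). Counts without a second value were the same adjusted over the list alone. At an unadjusted p under 0.05, limma found 1 lower gene in the TCA cycle list, 2 in the intestine list, 3 in the apoptosis list and 4 in the transthyretin-like list, and 0 higher vitellogenin genes. The camera adjusted p of the 30 lists that did not pass ran from 0.126 to 0.968. Median and mean differed in sign in the embryo (0.02 and -0.01), fat (-0.01 and 0.03), C-type lectin (-0.02 and 0.09) and F-box lists (-0.02 and 0.04). Camera gave embryo and fat as down and the other pair as up.

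Tests by numbered gene family, in 165 families of at least 10 genes and in both directions (330 Fisher's exact tests), were run without a fixed list. Major sperm protein genes rose more often than other genes (14 of 23, adjusted p = 2.35e-10), as did the him genes, named for a high incidence of males and mostly acting in meiosis (5 of 11, adjusted p = 0.0229). The patched-related ptr genes fell more often (5 of 24, adjusted p = 0.0229), as did the spig genes (4 of 14, adjusted p = 0.0229). Genes are not independent replicates. Some genes with several probe sets gave discordant values, of which a pair was chosen after their values were seen. The collagen gene sqt-3 stood at -4.48 ± 0.29 on its dimmer probe set and -0.56 ± 0.25 on the brighter, marked as shared. Likewise col-109 stood at -4.30 ± 0.24 on its dimmer probe set and -0.13 ± 0.31 on the brighter.

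Bacterial poly-A transcripts named dap, lys, phe and thr, which are spiked into RNA before labelling in this kind of protocol, were brighter on the ground arrays by 1.65, 2.06, 2.04 and 2.1-fold, without overlap between groups. The hybridisation controls bioB, bioC, bioD and cre were brighter there by 1.33, 1.39, 1.33 and 1.32-fold, without overlap for bioC. Relative to the hybridisation controls the spiked transcripts were 0.54 log2 units higher on the ground arrays, with overlapping arrays.

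Of the tests on germline and cuticle genes, those on somatic lists, on the sperm list and with the 5'/3' covariate were chosen after the result was seen, as were all those on defence genes, and the pooled gene groups were set after the list results were known. The 156 genes of the germline and meiosis, oocyte and eggshell, major sperm protein and cell cycle lists (median 1.00) exceeded the 183 genes of the collagen and moulting lists (median -0.33) by 1.34 in median (95% bootstrap interval over genes 1.14 to 1.51), and by 1.2 (1.06 to 1.45) with the sperm list in place of the cell cycle list, whose genes also act in somatic cells. Genes in the upper 1/3 of level gave 1.46 (1.23 to 1.77), which argues against a loss of dim transcripts as the whole cause. Quantile normalization left 1.26 (1.03 to 1.42). A single scaling factor per array nearly cancels in a difference of medians, so this value bears only on scaling that varies with intensity. RNA integrity cannot be told apart from the groups, since the actin 5'/3' ratio differed between them without overlap; the slope on that ratio within groups gave a share of 0.00531 of the group difference (-0.321 to 0.331). With arrays labelled technical replicates, that slope may read technical variation alone. The sources do not say whether arrays of a group shared 1 extract, so no conclusion on RNA integrity is drawn from it. With the mean 5'/3' ratio as covariate, which reads the same kind of slope, camera called germline and meiosis (median 1.16), major sperm proteins (1.34), oocyte and eggshell (0.80), the cell cycle (0.80), collagens (-0.34) and moulting (-0.51). Among genes in none of the 48 lists, 57 germline genes had a median of 0.67 (46 higher, 19 rose) and 149 cuticle and apical matrix genes a median of -0.283 (3 rose, 11 fell), at percentiles 100 and 0 of 10000 matched random lists. The germline values go with a larger germline share in the flown sample, as a hypothesis. The median of the 149 cuticle and apical matrix genes lay close to the -0.263 of 184 muscle, pharynx, hypodermis and neuron genes. It therefore does not single out cuticle-making stages. RNA integrity, a change of worm ages, fewer cuticle-making stages and a change within cells stay open. The arrays are labelled technical replicates and the number of cultures is unstated.

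A larger germline share that only diluted somatic RNA would lower somatic lists alike. The intestine median exceeded that of 184 muscle, pharynx, hypodermis and neuron genes by 0.359 (0.0771 to 0.623), so these lists did not fall alike. The intestine list itself stood apart neither in camera (adjusted p = 0.258) nor from matched random lists (adjusted p = 0.384), and 4 of its 30 genes rose. It may not read the gut's share of the RNA alone, so dilution stays open for the other somatic lists. Across the 48 lists the brightest member was higher on the space arrays in 12, so lower brightest members are not particular to germline genes. The brightest members of the germline and meiosis list did not move as one. The P granule helicase gene glh-1, chosen after its values were seen, rose by 1.17 ± 0.22, while gld-2, ekl-1, him-17 and nos-3 stood at -0.84, 0.03, -0.55 and 0.06. This list shared 1 gene with the DNA repair list, 1 with the DNA damage list and 0 with the cell cycle list.

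The fall of epidermal antimicrobial peptides (18 nlp and cnc genes, 11 fell and 1 was higher, median -1.55) stood beside 75 other defence genes, of which 13 rose and 38 were higher, with a median of 0.01. The median of the 18 peptide genes lay below that of 24 hypodermis genes outside the collagen list by a difference of -1.24 (-1.63 to -0.441). That interval treats the genes as independent, though all but 8 of the 18 were read by probe sets marked as shared. It therefore cannot decide whether a lower epidermal share of the RNA is the whole cause. The 8 members read without marked probes, of which 4 fell and 1 was higher, had a median of -1.15 (-3.11 to -0.125). This argues against signal shared between near-identical peptides as the whole cause of the lower median. These 8 include cnc-4 and nlp-25, already among the largest falls of all genes. Their interval includes the hypodermis median of -0.304, so by themselves they do not show a fall beyond that of the hypodermis genes. Quantile normalization gave -1.62 (-1.96 to -0.808). The array medians already lay close together, so this value says little on the scaling. It starts from the deposited intensities and cannot read earlier steps of processing. A change in the defence or osmotic state of the epidermis may be involved and was not tested.

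Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05, and 1 of them, the real one, gave as many. The real split called 2042 probe sets, 1648 at 2-fold, and 18 lists, and the highest other split 0, 0 and 13. The other 9 splits had 342 to 1668 probe sets at an unadjusted p under 0.05 in limma, against 5553. Each side of these 9 splits holds unequal numbers of space and ground arrays, so part of the group difference remains in them. It also adds to the spread within their sides. Their 4 to 13 lists therefore cannot show how readily camera calls lists where the groups do not differ.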
